A study of Mus musculus with 12 samples.

How the data were processed

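Chromatin accessibility was measured by ATAC-seq, in which the Tn5 transposase inserts sequencing adapters into open DNA, in 6 samples of mouse skin cells that fall into 5 groups. The normal groups are hair follicle (HF) and interfollicular epidermis (IFE) of wild-type mice, with 1 sample each. The tumour groups come from squamous carcinomas with floxed p53 alleles and a YFP reporter, started by a Cre recombinase under the K14 promoter of basal keratinocytes or the Lgr5 promoter of hair follicle stem cells. They are K14 Epcam+ (1 sample), Lgr5 Epcam+ (2 samples) and Lgr5 Epcam- (1 sample). Per the labels, cells were sorted with antibodies against CD45, CD31, CD140a and Epcam, libraries were made with a Nextera kit, and all mice are female and of mixed strain. Each sample was sequenced in a single-end and a paired-end run.

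The deposited tables, 12 in number, hold raw counts per peak, which is the unit the authors chose, for 1 shared list of 177240 peaks, followed by the HTSeq summary of counts that fell in no peak. Per the submitters' processing notes, reads were handled with Bowtie2, HOMER, bedtools and HTSeq on the mm10 build; versions, read filters, duplicate removal and how the peaks were called and pooled are not given in the sources used here. The peaks are 661 to 7053 bp wide (median 1097 bp) and cover 206.4 Mb.

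The 2 runs of a sample were summed and treated as 1 sample, because the titles differ only in read layout. Counts per peak were compared between groups with edgeR 4.0.16 (limma 3.58.1, R 4.3.3): filterByExpr with a minimum count of 10, which kept 177238 peaks, TMM scaling, a robust quasi-likelihood fit over all 6 samples and the quasi-likelihood F test, with Benjamini-Hochberg adjustment and a threshold of 0.05. Of 7 comparisons, 4 involve the Lgr5 Epcam+ pair and were tested this way. That pair gives the 1 residual degree of freedom, so each lone sample was assumed to vary as the pair does. The biological coefficient of variation was 0.325. The other 3 comparisons set 1 sample against 1 and were given no p-value by choice, since neither side holds a replicate, although the fit yields one under the same assumption. In them a peak was called by a rule of size: an absolute log2 ratio of TMM-scaled CPM (prior count 2) of at least 2 on the summed runs and of at least 1 in the same direction in each run. The same rule applied to Lgr5 Epcam+ sample 1 against sample 2 gives the background of the rule.

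A table of genes on the coordinates of mm10 carries no strand, so transcription start sites were not known, and each peak was assigned to the nearest protein-coding gene span within 50 kb. This replaced a planned assignment to start sites, and a planned division into promoter and distal peaks became gene end (within 1 kb of either end), inside a gene, within 50 kb, and far. Of the peaks, 146459 (82.6%) had a gene, and 18062 of 21887 genes had a peak. Counts were summed per gene and compared as above (18060 genes kept by the filter); the rule of size for genes asks for a log2 ratio of at least 1, and 0.5 in each run. The 18 gene lists, the comparisons, the tests and the rule for naming genes were set before the data were examined. Of 262 list entries 261 were matched by symbol; Krt85 was not, and Ctgf was read as Ccn2. The lists are EMT transcription factors, mesenchymal markers, epithelial adhesion and identity, basal keratinocyte, hair follicle stem cell, upper follicle and sebaceous, hair shaft and companion lineages, epidermal differentiation, squamous stress and wound response, AP-1 family, TGF-beta pathway, Ras-MAPK feedback targets, p53 targets, immune markers, endothelial markers, fibroblast and pericyte markers, melanocyte and Schwann cell markers, and housekeeping. The immune, endothelial and fibroblast lists were set for the cell types of the CD45, CD31 and CD140a antibodies, taken here as gated against. The fibroblast list also holds pericyte genes. Each list's median log2 ratio was placed among 10000 random lists of the same size, matched on mean log2 CPM in 20 bins. In tested comparisons, members were also adjusted over the list alone.

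Genes are named by rule: per list and comparison up to 4 passing members with the largest absolute log2 ratio and up to 2 that did not pass, with Epcam, Cdh1, Krt14, Krt5, Trp63, Grhl2, Lgr5, Krt15, Vim, Zeb1, Zeb2, Twist1, Twist2, Snai1, Prrx1, Fosl1, Ptprc, Pecam1, Pdgfra and Trp53 always allowed. Peaks are named by rule as the 6 higher and 6 lower with the largest absolute log2 ratio among called peaks of above-median mean level with a gene within 50 kb, 1 per gene. Peak sets (EMT peaks, defined as peaks higher in Lgr5 Epcam- than in HF, and peaks that differ between HF and IFE) were placed among 10000 random peak sets matched in the same way. Scans along chromosomes for steps and for high or low stretches used log2 of counts plus 2, centred on the median of each sample, in place of TMM.

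Alternatives were total-count scaling, DESeq2 1.42.0 size factors, loess scaling, no filter, each run alone, the DESeq2 Wald test, the rule of size in place of the test, log2 limits of 1 and 3, a prior count of 5, leaving out either Lgr5 Epcam+ sample, and gene distances of 10 and 100 kb. After the data were seen, further ones were added: centring every sample in windows of 5 Mb, chromosomes 1 to 14 alone, leaving out 79 pile-up peaks whose paired-end counts exceed 3 times their single-end counts, subtracting the background counted outside peaks, and paired-end gene sums. The procedure was tested on simulated data with known changes, drawn from the fitted dispersions. There, edgeR found 25.4% of 4-fold and 54.5% of 8-fold changes in Lgr5 Epcam+ against HF, 12.1% and 50.7% in Lgr5 Epcam- against Lgr5 Epcam+, 5.97% and 64.2% in Lgr5 Epcam+ against K14 Epcam+, and 0 and 7.58% for the difference between the tumour changes, with at most 6 false calls. The rule of size made 1010 to 1231 false calls in simulated 1 against 1 comparisons. Simulated runs of a sample differed by counting error only, unlike the measured runs. The simulated Lgr5 Epcam+ pair gave 1010 calls and the measured pair 769 higher and 1705 lower, so the simulated numbers do not replace the measured background. Of 100 unshifted random lists, 5 fell outside the central 95% of percentiles. Tables were read and drawn with Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

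Counts in peaks per sample ran from 32086654 to 62941406, so a peak at the median had 90 to 149 counts. Intervals given for shares and for single peaks are 95% intervals that cover counting error only, since reads without molecular identifiers are not independent molecules. A motif comparison was planned and not run, because no genome sequence was at hand. Splits of the samples into other groups were not tried, since no group holds 3 samples.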

Results

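ATAC-seq counts over 177240 peaks were compared in normal hair follicle (HF, n = 1), normal interfollicular epidermis (IFE, n = 1), Epcam-positive cells of K14-Cre tumours (K14 Epcam+, n = 1), and Epcam-positive (n = 2) and Epcam-negative (n = 1) cells of Lgr5-Cre tumours (Lgr5 Epcam+ and Lgr5 Epcam-). Epcam is a surface protein of epithelial cells. Its absence is read here as a sign of the epithelial to mesenchymal transition (EMT) named in the series title. Whether the Epcam-negative cells are tumour cells that left the epithelial state, or in part stromal cells, was not tested. Summed counts in peaks were 32086654 in HF, 34040799 in IFE, 39179299 in K14 Epcam+, 41252832 in Lgr5 Epcam-, and 62941406 and 45718546 in Lgr5 Epcam+ samples 1 and 2. The share of counts that fell in peaks ranged over the 12 runs from 20.9% (HF, single-end) to 48.3% (Lgr5 Epcam+ sample 1, paired-end), with 95% Wilson intervals of at most 0.0132 percentage points to either side. Background expected inside peaks, from the density of counts outside them, amounted to 26% of the peak counts in HF and 19.5% in IFE. In K14 Epcam+ it was 14.9%, in Lgr5 Epcam- 15.6%, and in the Lgr5 Epcam+ samples 9.16% and 11.4%, for an assumed genome of 2722 Mb. Apart from Lgr5 Epcam+, no group had a replicate, and nothing in the labels says that the Lgr5 Epcam+ samples are separate animals. The p-values therefore measure only the spread between these samples, which may be technical.

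On log2 CPM over peaks, the tumour samples stood apart from the normal ones (Pearson r across peaks 0.406 to 0.592) along a first principal component with 51.9% of the variance. The second component (26.3%) set Lgr5 Epcam- apart from the Epcam+ tumours. K14 Epcam+ had r = 0.918 with Lgr5 Epcam+ sample 1 and 0.860 with sample 2, against 0.899 between these samples, while Lgr5 Epcam- had r = 0.672 and 0.691 with them. HF and IFE had r = 0.825. Peaks are not independent replicates. One technical feature bears on every value of K14 Epcam+. From position 31571653 of chromosome 15 through X, its single-end counts were lower than its paired-end counts by a log2 step of -0.93. On chromosomes 16 to X, the share of its counts was 8.37% single-end and 14.8% paired-end (95% Wilson intervals of at most 0.0180 points to either side). The trace of single-end against paired-end counts shows the step, which no other sample had.

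**Figure D1:**
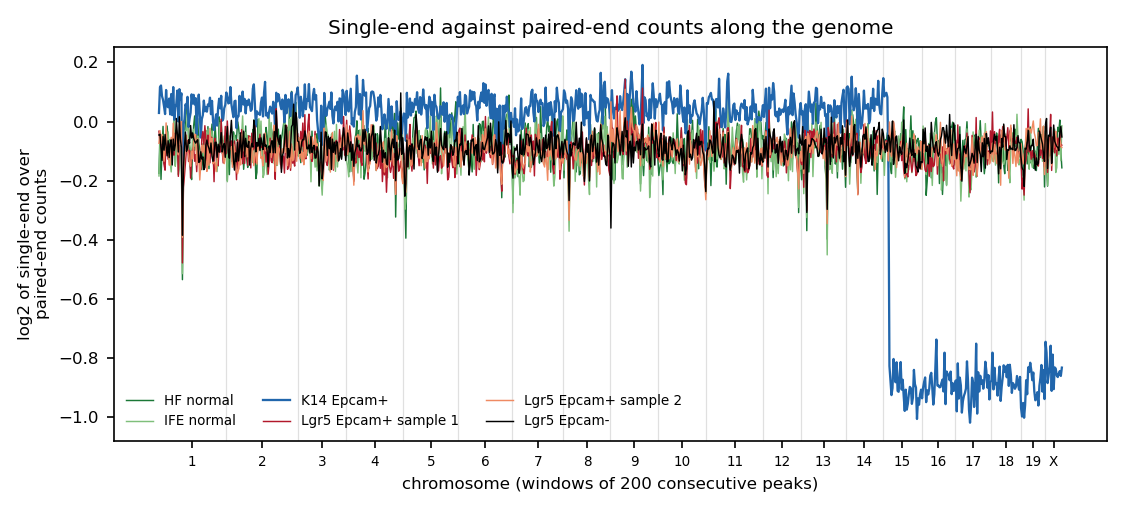
Log2 of single-end over paired-end counts (y axis) in 886 windows of 200 consecutive peaks ordered along the genome (x axis, chromosomes), with 1 line per sample. The K14 Epcam+ line steps by -0.93 at position 31571653 of chromosome 15, and the largest step found in any other sample is 0.036.

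The comparison of HF with IFE asks how the accessible chromatin of these normal epithelia differs. Genes of hair follicle stem cells were more accessible in HF. Lgr5, a receptor that marks follicle stem cells, had 217 CPM over its peaks in HF and 48.4 in IFE (log2 ratio 2.16). Lhx2, a transcription factor that keeps follicle stem cells quiescent, had a log2 ratio of 1.59, the transcription factor gene Tbx1 2.11 and the growth factor gene Fgf18 1.20. Genes of epidermal differentiation were less accessible in HF, with log2 ratios of -1.66 for Krt1 and -1.18 for Krt10, the keratins of the suprabasal epidermis, -1.56 for Zfp750, a regulator of terminal differentiation, and -1.16 for Casp14, a protease of cornification. Of 16 hair follicle stem cell genes 4 were called higher and 0 lower (median 0.71, above all 10000 random lists), and of 20 differentiation genes 0 were higher and 5 lower (median -0.53, below all random lists).

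Other lists moved less between the normal samples, and gene calls near the limit of 1 do not stand apart from the background of the rule, given below. Of 17 mesenchymal markers 3 were higher in HF (Postn 1.16, Col1a2 1.07 and Fbn1 1.02, all matrix genes) and 0 lower. Of 15 TGF-beta genes 2 were higher (Ccn2 1.60, Ltbp2 1.33), of 12 EMT transcription factors 1 (Hmga2 1.02), of 20 stress genes 1 (Krt6a 1.29) and of 12 endothelial markers 1 (Sox17 2.27; list median 0.37, percentile 99.73 of random lists). Among hair shaft genes Hoxc13 (1.35) was higher and Krt35 (-1.50) lower, and of 15 measured immune markers 0 were higher and 1 lower. Sox9 (0.87), Cd34 (0.96) and Zeb1 (0.79) did not reach the limit, nor did Krt15 (0.29) and Krt14 (-0.10). No member was called in the epithelial adhesion, basal keratinocyte, upper follicle, AP-1, Ras-MAPK, p53, fibroblast, melanocyte and housekeeping lists, although the epithelial adhesion list had a median of -0.26 (percentile 0.07 of random lists, 22 of 25 genes below 0) and the fibroblast list one of 0.3 (percentile 99.28, 11 of 12 above 0); that of the EMT transcription factors was 0.36 (percentile 99.91). Among called peaks of above-median mean level with a gene within 50 kb, the largest ratio lay near Clnk on chromosome 5 (38902626 to 38903626, log2 4.08, 95% interval 3.74 to 4.53). The lower ones included a peak near Hes5, a Notch target, on chromosome 4 (154947801 to 154949140, -2.61, -2.95 to -2.33).

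In all, 2745 peaks were higher and 939 lower in HF by the rule of size, and 467 genes higher and 268 lower. Peaks far from genes made up 34.1% of the higher and 21.3% of the lower peaks, against 17.4% of all tested peaks, and peaks at gene ends 1.46% and 4.05%, against 9.50%. The same rule called 769 peaks higher and 1705 lower between the Lgr5 Epcam+ samples, and 285 genes higher and 498 lower, where the order of the samples is arbitrary, and far peaks were 20.7% of these higher and 37.4% of these lower peaks. At gene level the rule thus made more calls within this group than between HF and IFE. Higher peaks were 74.5% of the calls with TMM and 87.6% with total-count scaling, but 47.6% at a log2 limit of 1 (13352 and 14671).

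The comparison of K14 Epcam+ with IFE sets a tumour against normal epidermis. Genes of the wound and stress response of squamous epithelia were more accessible in the tumour: of 20, 16 were called higher and 0 lower (median log2 ratio 1.68, above all random lists). The neutrophil chemokine gene Cxcl2 had a log2 ratio of 2.72, the cornified envelope gene Sprr1b 2.26, the urokinase receptor gene Plaur 2.26 and the protease gene Mmp10 2.24. Of 12 EMT transcription factors 6 were higher and 0 lower (median 0.98), among them Zeb2 (1.74), Prrx1 (1.66), Twist2 (1.5), Twist1 (1.47) and Snai1 (1.39). Of 20 differentiation genes 0 were higher and 7 lower (median -0.57), led by Krt1 (-2.96), the desmosomal cadherin gene Dsg1a (-2.51), Krt10 (-2.31) and Casp14 (-1.91). Krt1 lies on chromosome 15, which holds the single-end step and had a median of -0.34 over all peaks. Krt15, a keratin of basal and follicle stem cells, had -2.88.

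Of 15 TGF-beta genes 4 were higher and 0 lower (median 0.88; Smad3 1.08), and of 14 Ras-MAPK feedback genes 3 were higher (Phlda1 2.12, Dusp4 1.34, Dusp6 1.23) and 0 lower. Fosl1 (1.45, and 1.82 in the paired-end run), an AP-1 subunit on chromosome 19, and Batf (1.3) were the 2 higher members of the AP-1 family. Epithelial adhesion genes went both ways, with 3 higher, including the claudin genes Cldn7 (1.72) and Cldn4 (1.66), and 2 lower of 25; Cdh1, the E-cadherin gene, had -0.04 and Epcam 1.04 (1.53 paired-end). No basal keratinocyte gene and no p53 target was called, with Krt5 at -0.71, Trp63 at -0.69 and Krt14 at 0.33. Krt5 and Trp63 lie after the single-end step, where the counts of this sample were low. Mesenchymal markers gave 2 higher (Fbn1 1.32, Vim 1.3) and 1 lower (Thy1 -1.57). Markers of the cell types that the other sort antibodies address moved as well. Of these, 4 endothelial markers were higher and 0 lower (Cdh5 1.81, Tie1 1.74, Emcn 1.65, Kdr 1.1). Immune markers gave 4 higher and 2 lower (Ptprc 1.56, Cd68 1.26), and fibroblast markers 2 higher and 1 lower (Col6a3 1.13). Of the remaining lists, hair follicle stem cell had 3 higher and 1 lower, upper follicle 2 and 0 (Pparg 2.21), hair shaft 1 and 3, melanocyte 0 and 1, and housekeeping 0 and 0.

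By the rule of size, 13016 peaks were higher and 10401 lower in K14 Epcam+, but 9197 and 10613 with loess scaling. A peak near Krt15 on chromosome 11 (100129594 to 100130852) had 48.9 CPM in IFE and 1.32 in K14 Epcam+ (log2 -5.21, 95% interval -5.70 to -4.86), and 1 inside Kank1 on chromosome 19 (25336618 to 25337676) had -5.23. A peak inside Etv6 on chromosome 6 (134082116 to 134083250) had 4.76 and 1 inside Eps8 on the same chromosome 4.73. Both lie in a stretch of chromosome 6 where the median log2 ratio over all peaks was 0.75 (120 to 130 Mb), 0.91 (130 to 140 Mb) and 0.91 (140 to 150 Mb). On chromosomes 15 to 19 and X, at and after the single-end step, medians were -0.34 to -0.59. In the paired-end run, Zeb1 (0.57 on summed runs) had 1.08 and Itga5 (0.85) had 1.31. On chromosomes 1 to 14 alone 10305 peaks were higher and 7828 lower.

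The comparison of Lgr5 Epcam+ (n = 2) with HF (n = 1) is the same contrast for tumours begun from Lgr5-expressing follicle cells. The stress and wound genes rose as a group, 16 of 20 with 0 that fell (median log2 ratio 1.77, above all random lists; 17 and 0 adjusted over the list alone). Cxcl2 rose by 2.51 ± 0.37 (SE, edgeR adjusted p = 0.00244), Sprr1b by 2.48 ± 0.40, Mmp10 by 2.33 ± 0.33 (adjusted p = 0.00197) and the chemokine gene Cxcl1 by 2.13 ± 0.35. Of 12 EMT transcription factors 5 rose and 0 fell (median 0.67; 6 and 1 adjusted over the list alone), namely Snai1 (1.88 ± 0.33, adjusted p = 0.00500), Twist2 (1.42 ± 0.32), Twist1 (1.36 ± 0.31), Zeb2 (1.26 ± 0.33) and Prrx1 (1.18 ± 0.33). Of 16 hair follicle stem cell genes 0 rose and 4 fell (median -0.55, below all random lists; 0 and 6 adjusted over the list alone): Krt15 fell by 3.01 ± 0.30 (adjusted p = 0.000504), Lhx2 by 2.22 ± 0.29, Lgr5 by 1.72 ± 0.31 (adjusted p = 0.00508) and Nfatc1, a factor of stem cell quiescence, by 1.0 ± 0.30.

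Fosl1 rose by 2.01 ± 0.40 (adjusted p = 0.00908), and with Batf (1.24) was the called part of the AP-1 family (2 higher and 0 lower of 9; 3 and 0 adjusted over the list alone). Epithelial adhesion genes gave 3 higher and 0 lower in both counts, namely Cldn4 (1.89), the desmocollin gene Dsc2 (1.59) and Epcam (1.11 ± 0.32, adjusted p = 0.0417). Vim rose by 1.31 ± 0.33, while the mesenchymal genes Col1a2 (-1.84) and Thy1 (-1.62) fell (1 and 2; 1 and 3 adjusted over the list alone). Of 15 TGF-beta genes 2 rose (Tgfb1 1.53 among them) and 0 fell (5 and 1 adjusted over the list alone), and Phlda1 (1.77), Dusp4 (1.28) and Dusp6 (1.25) were the 3 rising Ras-MAPK genes (3 and 0). Hair shaft genes gave 0 higher and 3 lower (Hoxc13 -1.86, Msx2 -1.56, Gata3 -1.04; 1 and 4 adjusted over the list alone). Of the p53 targets Pmaip1 (1.27) rose (1 and 0). Differentiation genes gave 1 and 1 (Zfp750 1.19, Dsg1a -1.59; 2 and 1), and the upper follicle list 1 and 0 (2 and 0). Basal keratinocyte genes gave 0 and 0 in both counts (median 0.54; Krt14 0.71, Krt5 -0.04, Trp63 0.06), and Cdh1 had 0.14 ± 0.31. Among markers of other cell types, Ptprc (1.28), the pan-leukocyte gene of the CD45 gate, rose as 1 of 15 immune markers (2 and 0 adjusted over the list alone), endothelial markers gave 2 higher (Tie1 1.73, Flt1 1.20) and 2 lower (Sox17 -3.21, Tek -2.02; 2 and 2), fibroblast markers 1 and 0 (Col6a3 1.31; 1 and 1), melanocyte markers 0 and 0 (0 and 2), and housekeeping genes 0 and 1 (0 and 1 adjusted over the list alone).

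In edgeR, 15737 peaks rose and 13130 fell, and 1039 genes rose and 903 fell (382 and 686 genes with total-count scaling, 620 and 689 with loess scaling). The peak near Krt15 had 52.0 CPM in HF and 1.27 and 1.76 in the Lgr5 Epcam+ samples (log2 -5.15 ± 0.39), the peak inside Kank1 had -5.31 ± 0.39, and a peak inside Mtss1 on chromosome 15 (58997660 to 58998678) rose by 5.07 ± 0.47 (adjusted p = 0.000191). A peak near Col19a1 with 5.46 ± 0.17 is a site of paired-end pile-up, described with the difference between the tumour changes. Peaks at gene ends were 7.74% of the rising and 3.57% of the falling peaks, and far peaks 19.3% and 26.3%. The split depended on the method: rising peaks were 54.5% of the calls with TMM, 37.2% with total-count scaling, which shifted the median of all genes to -0.11, 39.7% with loess scaling and 71.2% with the DESeq2 test (18435 and 7454). Chromosome 9 as a whole had a median of -0.47, and with samples centred in windows the median of the hair follicle stem cell list was -0.12.

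**Figure D2:**
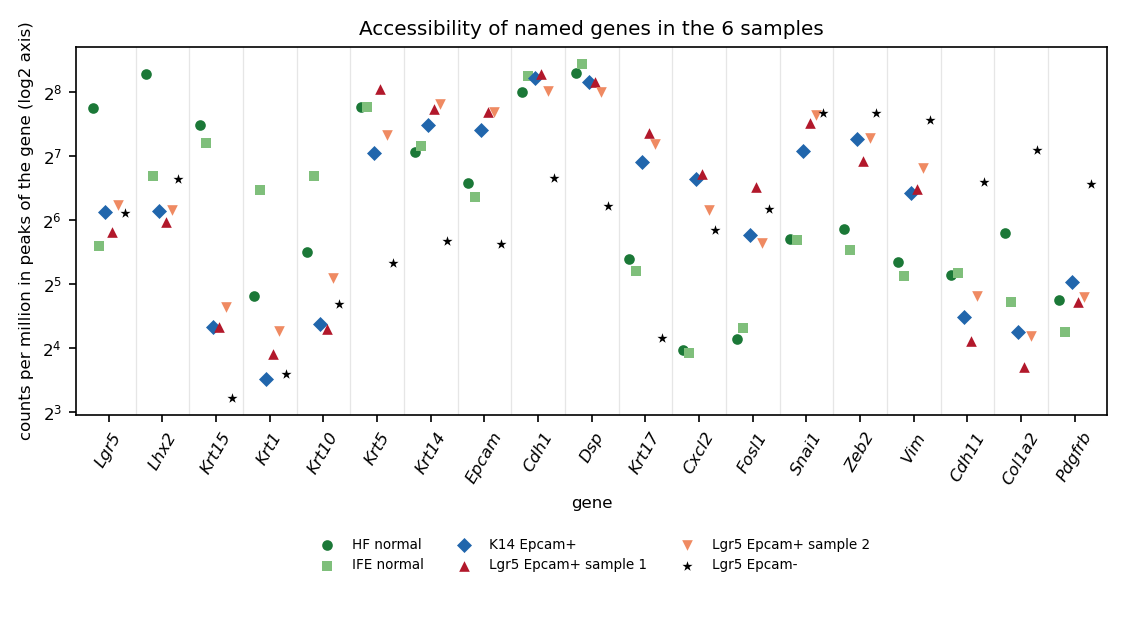
CPM summed over the peaks of 19 genes (x axis) in each of the 6 samples (y axis, log2 scale; 1 point per sample, no error bars because only Lgr5 Epcam+ has 2 samples). Krt15 is at 180.2 CPM in HF and 9.27 CPM in Lgr5 Epcam-, and Col1a2 is higher in Lgr5 Epcam- (136 CPM) than in the other 5 samples (13.0 to 55.7 CPM).

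The comparison of Lgr5 Epcam+ (n = 2) with K14 Epcam+ (n = 1) asks whether epithelial tumour cells keep a difference by cell of origin. No member of any of the 18 lists passed the test, over all genes or adjusted over the list alone. EMT transcription factors had the highest list median relative to random lists, 0.39 (percentile 99.9), which was 0.19 with samples centred in windows and 0.16 with peaks within 10 kb of the gene, followed by epidermal differentiation with 0.25 (percentile 98.06, 18 of 20 genes above 0). Members of the EMT list with the largest values were Snai2 (0.90 ± 0.30, and 0.65 in the paired-end run; adjusted p = 0.562) and Foxc2 (0.71), and Twist1 had 0.36 ± 0.30, Zeb1 0.57 ± 0.34 and Vim 0.23 ± 0.31. The medians of the endothelial (-0.35, percentile 0.26; Kdr -1.07), fibroblast (-0.29, percentile 0.45; Rgs5 -1.09) and immune lists (-0.29, percentile 5.73; Tyrobp -1.88 ± 0.57) were on the other side, and that of the stress list was 0.054. For scale, between Lgr5 Epcam+ samples 1 and 2 the list medians were 0.48 for stress genes (above all random lists), -0.28 for mesenchymal markers (percentile 0.28), -0.26 for hair follicle stem cell genes (percentile 0.27) and -0.18 for EMT transcription factors, so samples of 1 group also reach the ends of the random lists. Values of genes after the single-end step were smaller in the paired-end run, for Trp63 0.38 against 0.71, for Krt5 0.35 against 0.68 and for Krt6a 0.57 against 0.88. Zeb1 also lies after the step, on chromosome 18, where all peaks had a median of 0.39. Its paired-end value in this comparison is not given here, and its ratio of K14 Epcam+ to IFE was larger in the paired-end run. Lgr5, which was higher in HF than in IFE, had -0.08 ± 0.32, Krt15 0.17 ± 0.31 and Epcam 0.29 ± 0.31.

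In edgeR 1 peak rose and 14 fell, at 10019 peaks with an unadjusted p under 0.05, and DESeq2 called 30 higher and 24 lower. The rising peak is the pile-up site near Col19a1. Of the 14 falling peaks, 11 had at most 8 counts in each of the 3 Lgr5 libraries, Lgr5 Epcam- included. The peak near Map3k7 (chromosome 4, 32046642 to 32047663) had 24 counts in HF, 14 in IFE, 160 in K14 Epcam+ and 0 in each Lgr5 library, and the peak near Api5 (chromosome 2, 94449409 to 94450409) had 43, 28 and 162 and then 0, 0 and 1. At gene level 1 rose (Col19a1) and 6 fell (5730507C01Rik, Gm51598, Igsf9b, Mrgprb13, Speer3 and Tpbpa, chosen after their values were seen), of 1276 with an unadjusted p under 0.05, but only 1 fell with total-count scaling, with loess scaling, with peaks within 10 kb and with samples centred in windows. Falling peaks were 14 with TMM and 0 with samples centred in windows.

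Whether the tumours kept the HF against IFE difference was also examined over peak sets. Across all peaks, log2 Lgr5 Epcam+ over K14 Epcam+ had Pearson r = 0.038 and Spearman rho = 0.014 with log2 HF over IFE. Of 2745 peaks higher in HF, 59.3% were higher in Lgr5 Epcam+ than in K14 Epcam+ (median log2 ratio 0.15, above all random sets), and of 939 peaks higher in IFE 59.0% were lower (median -0.13, below all random sets). The HF-higher peaks, whose high level in HF and low level in IFE come in part from their selection, had a median log2 CPM of 3.38 in HF, 0.86 in IFE, 0.48 in K14 Epcam+, and 0.36 and 0.84 in Lgr5 Epcam+. One library decides the share for the HF-higher peaks, which was 45.5% with Lgr5 Epcam+ sample 1 alone (r = -0.040) and 69.1% with sample 2 alone (r = 0.096).

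The series title asks whether cell types differ in how they are primed for EMT. The 12533 peaks higher in Lgr5 Epcam- than in HF are low in HF by their selection, and a set chosen against normal skin also takes in any general change of tumours, so their level in Epcam+ tumours does not measure priming. Their median log2 CPM was 0.90 in HF, 0.74 in IFE, 2.54 in K14 Epcam+, 2.56 and 2.5 in Lgr5 Epcam+ and 3.46 in Lgr5 Epcam-, while that of all peaks was 1.37 to 1.57. Between the Epcam+ tumours these peaks went both ways, with 52.4% of them higher in Lgr5 Epcam+. Their median log2 ratio of Lgr5 Epcam+ to K14 Epcam+ was 0.036, below all matched random sets (95% of them from 0.062 to 0.084), and 0.063 and 0.015 with each Lgr5 Epcam+ sample. With total-count scaling it was -0.14, where the random sets had a median of -0.10.

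The comparison of Lgr5 Epcam- (n = 1) with Lgr5 Epcam+ (n = 2) sets Epcam-negative against Epcam-positive cells from tumours of 1 origin. Epithelial genes lost accessibility: of 25 adhesion and identity genes 14 fell and 0 rose (median -1.39; 20 and 0 adjusted over the list alone). Epcam itself fell by 2.06 ± 0.34 (adjusted p = 0.00483), the desmosomal genes Dsg3 by 2.19 ± 0.35 (adjusted p = 0.00430) and Dsp by 1.87, Cdh1 by 1.49 ± 0.33 and Grhl2, a regulator of epithelial identity, by 1.59. Mesenchymal markers gained, 9 of 17 with 0 that fell (median 1.3; 13 and 0 adjusted over the list alone): the collagen genes Col1a2 rose by 3.13 ± 0.30 (adjusted p = 0.000300) and Col3a1 by 2.67 ± 0.29, the smooth muscle gene Tagln by 2.21 and the cadherin gene Cdh11 by 2.10. Of 12 EMT transcription factors 1 rose and 0 fell in both counts; the list median was 0.49 (percentile 99.98), with Zeb1 at 0.79 ± 0.32, Prrx1 at 0.61, Zeb2 at 0.56, Twist1 at 0.56 and Snai1 at 0.09. Fn1 (1.3) and Vim (0.90 ± 0.30) did not pass.

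All members of the basal keratinocyte, differentiation and stress lists that passed fell. Of 15 basal keratinocyte genes 6 fell and 0 rose (median -1.10; 11 and 0 adjusted over the list alone), with Krt5 down by 2.40 ± 0.39, Krt14 by 2.11 ± 0.34 and the factor Tfap2c by 2.06, and Trp63 at -1.04 without passing. Of 20 differentiation genes 10 fell in both counts and 0 rose (median -1.02; Krtdap -2.85, Tgm1 -2.25, Abca12 -2.06, Zfp750 -2.04), and of 20 stress genes 7 fell and 0 rose (median -1.12; 12 and 0 adjusted over the list alone; Krt17 -3.12, Krt6a -2.91, Il24 -2.57, Krt16 -2.26). Hair shaft genes gave 0 higher and 2 lower in both counts (Krt75 -2.20, Krt71 -1.66), hair follicle stem cell genes 0 and 1 (Krt15 -1.28; 0 and 2), and upper follicle genes 0 and 1 in both (Plet1 -1.34). Of 12 fibroblast and pericyte markers 5 rose and 0 fell (median 0.92; 6 and 0 adjusted over the list alone), led by the pericyte genes Rgs5 (2.80), Tbx18 (2.25) and Pdgfrb (1.81) and the matrix gene Lum (2.09), while Pdgfra, which encodes the CD140a of the gate, had 0.64 ± 0.29 and did not pass. Immune markers gave 1 and 0 in both counts (Csf1r 1.28; Ptprc -0.56 without passing) and endothelial markers 2 and 0 (Tek 1.17, Emcn 1.09, with Pecam1 at -1.03 without passing; 3 and 2 adjusted over the list alone). No member of the AP-1, TGF-beta, Ras-MAPK, p53, melanocyte and housekeeping lists passed in either count.

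In edgeR, 11854 peaks rose and 9343 fell, and 628 genes rose and 596 fell (418 and 234 genes with total-count scaling). DESeq2 called 5683 and 10101, so that rising peaks were 55.9% of the calls with the first and 36.0% with the second. Far peaks were 29.4% of the rising and 19.2% of the falling peaks. All 6 rising peaks named by the rule, near or inside Tmem123, Birc3, Smad6, Birc2, Dpy19l1 and Cep126 (log2 4.69 to 5.03), lie in 6 short segments of chromosome 9 that together hold 336 of the rising peaks and 1.15% of the counts of Lgr5 Epcam- (95% Wilson intervals of at most 0.00326 points to either side). Among the peaks named by the rule, the falling ones with the largest values lay inside Ppfibp2 on chromosome 7 (107685167 to 107686216, -4.40 ± 0.44) and Abca13 on chromosome 11 (-4.31 ± 0.66). With samples centred in windows Col1a2 was at 1.71 and Col3a1 at 1.63.

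**Figure D3:**
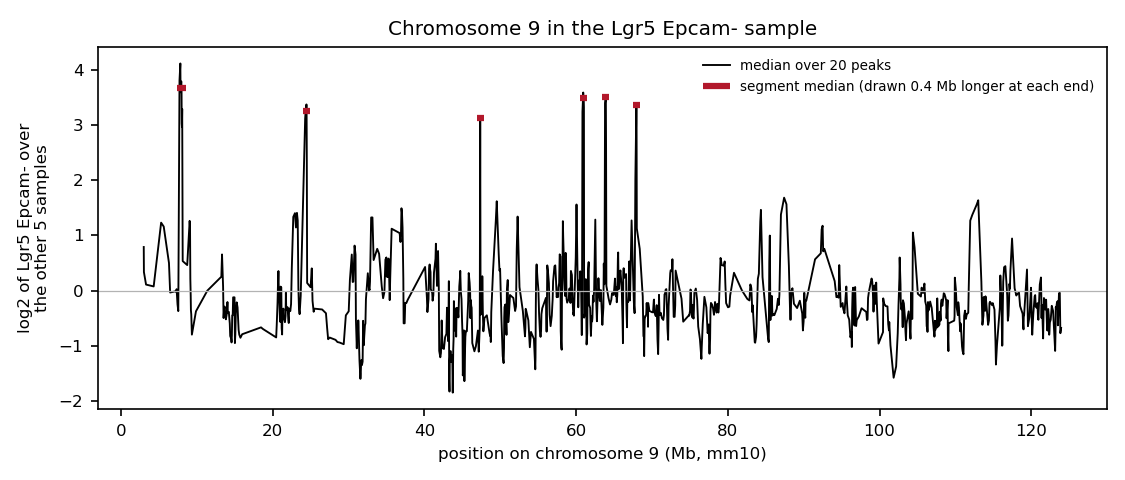
Log2 of Lgr5 Epcam- over the mean of the other 5 samples along chromosome 9 (x axis, Mb on mm10), as a running median over 20 peaks (black line) with the medians of the 6 high segments (red bars, drawn longer than they are). Segment medians are 3.12 to 3.67, and the rest of the chromosome has a median of -0.28.

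The comparison of Lgr5 Epcam- with HF sets the Epcam-negative cells of Lgr5-Cre tumours against normal follicle, with 1 sample on each side. Of 12 EMT transcription factors 6 were called higher and 0 lower (median 1.05), with Snai1 at 1.96, Twist1 at 1.92, Zeb2 at 1.82, Prrx1 at 1.79, Twist2 at 1.43 and Zeb1 at 1.13. Mesenchymal markers were 10 higher and 0 lower of 17 (median 1.25; the collagen cross-linking gene Lox 2.40, Vim 2.21, Col3a1 1.91), and fibroblast markers 6 higher and 0 lower of 12 (median 1.18; Lum 1.88, Pdgfrb 1.81). Epithelial adhesion genes were 0 higher and 10 lower of 25 (median -0.95), with Dsp at -2.08, Perp at -2.07, Cdh1 at -1.35 and Epcam at -0.95, which did not reach the limit. Differentiation genes were 0 and 9 (Krtdap -2.56, Sbsn -2.27), basal genes 0 and 5 (Krt5 -2.44, Krt14 -1.40), and hair follicle stem cell genes 0 and 4 (Krt15 -4.28, Barx2 -2.02, Lgr5 -1.64, Lhx2 -1.64). The stress list split into 6 higher (Cxcl2 1.88; Mmp13 1.63, which had 0.14 with samples centred in windows) and 3 lower (Krt6a -1.54), and Fosl1 was at 2.04. By the rule of size 12533 peaks were higher and 11211 lower, but 10310 and 13280 with total-count scaling and 10951 and 11656 with loess scaling. Of the higher peaks 325 lie in the chromosome 9 segments, among them a peak inside Yap1, a Hippo pathway coactivator (7978466 to 7980078, log2 5.75, 95% interval 5.55 to 5.98), with 275 CPM in Lgr5 Epcam-, 16 and 8.76 in the Lgr5 Epcam+ samples and 5.11 in HF.

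The last comparison asks whether the change from normal to tumour differs by origin, as the log2 ratio of Lgr5 Epcam+ to HF minus that of K14 Epcam+ to IFE. Over all genes, 0 list members passed. Adjusted over the list alone, 4 of 16 hair follicle stem cell genes were lower (list median -0.50, below all random lists) and 3 of 20 differentiation genes higher (median 0.96, above all random lists). Lgr5 had -2.25 ± 0.49 (edgeR adjusted p = 0.00801 over the list alone and adjusted p = 0.284 over all genes) and Krt1 2.25 ± 0.50 (adjusted p = 0.0114 and adjusted p = 0.284). Lgr5 and Krt1 differed between the normal samples more than between the tumours: Lgr5 was at 217 CPM in HF and 48.4 in IFE, against 56.1 and 75.4 in Lgr5 Epcam+ and 69.5 in K14 Epcam+, and Krt1 at 28.1 and 89.0, against 15, 19.3 and 11.4. The other lists had 0 members passing in either count; the largest medians among them were those of fibroblast (-0.68) and epithelial adhesion genes (0.46).

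By edgeR 1 peak differed and 0 in the other direction, at 11577 peaks with an unadjusted p under 0.05, and DESeq2 called 2 higher and 2 lower. This peak, near Col19a1 on chromosome 1 (24612392 to 24613443, log2 5.83 ± 0.21, adjusted p = 2.04e-07), had 26.1 CPM in HF, 78.4 in IFE, 60.9 in K14 Epcam+, 1130 in Lgr5 Epcam-, and 1035 and 1261 in Lgr5 Epcam+. It is 1 of 79 pile-up peaks, since its counts in the 3 Lgr5 libraries were 47182 to 56020 paired-end but 723 to 738 single-end. In the single-end runs alone this peak was not called. At gene level 1 gene passed, also Col19a1 (4.32, chosen after its value was seen), of 1151 with an unadjusted p under 0.05, and 0 passed with peaks within 10 kb, total-count scaling or loess scaling.

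**Figure D4:**
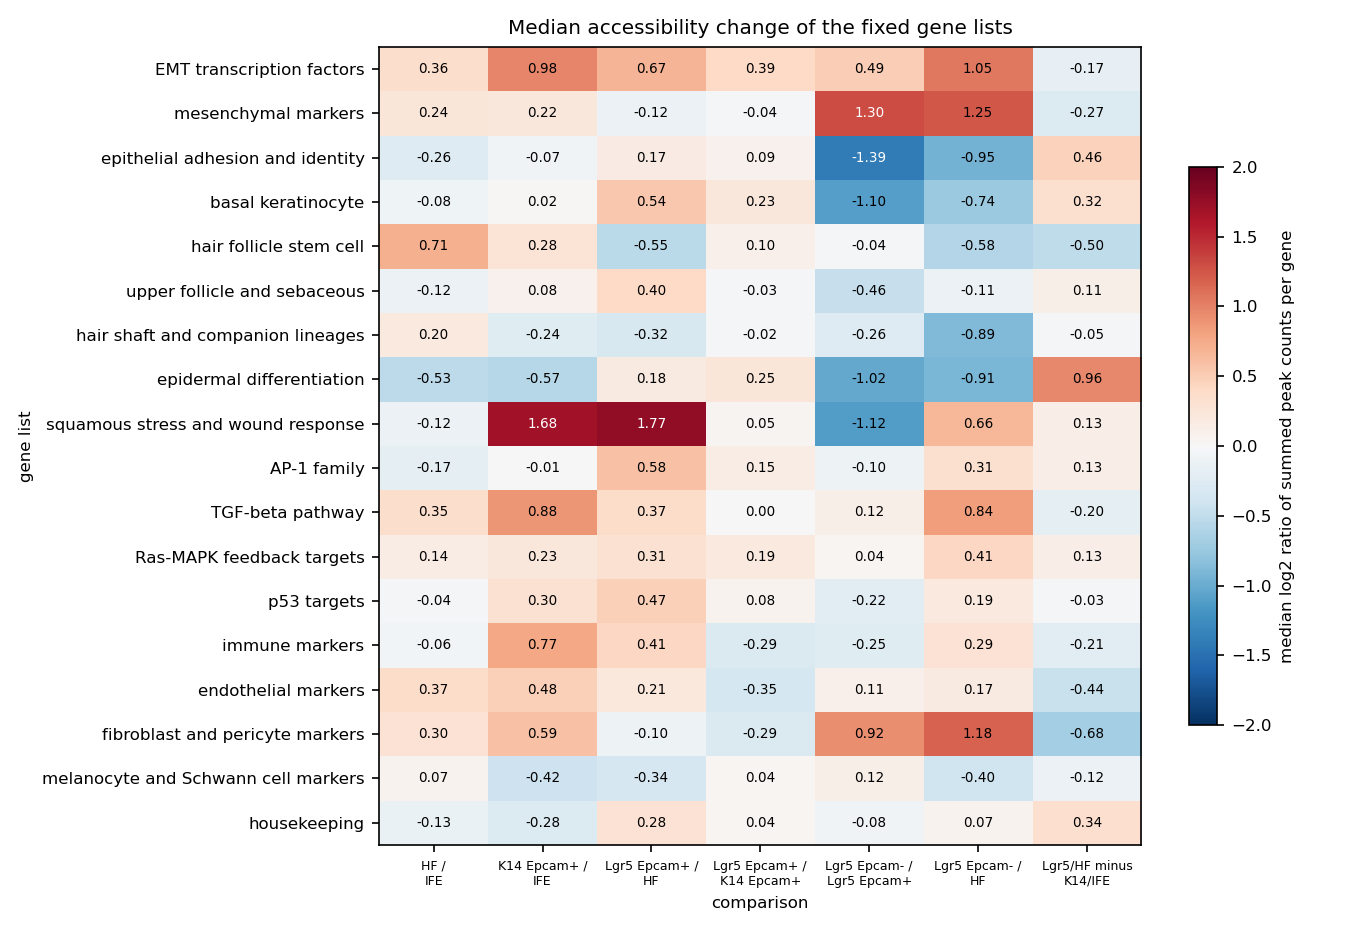
Median log2 ratio of summed peak counts per gene (colour and printed value) for the 18 gene lists (y axis) in the 7 comparisons (x axis). Stress and wound response genes have medians of 1.68 and 1.77 in the Epcam+ tumours against normal skin, and epithelial adhesion genes have -1.39 in Lgr5 Epcam- against Lgr5 Epcam+.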

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

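The test of the difference between the 2 tumour changes (Lgr5 Epcam+ against HF, minus K14 Epcam+ against IFE) was planned, and the look at single-end and paired-end counts of the peak near Col19a1 and the values from centred windows were chosen after its result was seen. What singles out the results here is that this difference itself passed a test, for 1 peak over all peaks, for 1 gene over all genes and for 7 genes when adjusted over the list alone.

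The peak near Col19a1 (chromosome 1, 24612392 to 24613443) differed by 5.83 (edgeR adjusted p = 2.04e-07). Its paired-end counts were 47182 to 56020 in the 3 Lgr5 libraries and 739 to 2461 in the other 3, while its single-end counts were 723 to 738 and 208 to 378, and in the single-end runs alone this peak was not called. The gene Col19a1, whose summed counts include this peak, differed by 4.32 (edgeR adjusted p = 0.0209 over all genes), and 0 genes passed with peaks within 10 kb of the gene, which leaves this peak out, or with total-count or loess scaling.

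Among hair follicle stem cell genes, the difference was -2.25 for Lgr5 (edgeR adjusted p = 0.00801 over the list alone and adjusted p = 0.284 over all genes, -2.53 in the paired-end run), -1.92 for Tbx1 (0.0180 and 0.438, -2.495 paired-end), -1.66 for Lhx2 (0.0180 and 0.454, -1.91 paired-end) and -1.37 for Fgf18 (0.0402 and 0.584, -1.47 paired-end). Among differentiation genes it was 2.25 for Krt1 (0.0114 and 0.284, 2.27 paired-end), 1.79 for Krtdap (0.0289 and 0.444, 1.98 paired-end) and 1.77 for Zfp750 (0.0289 and 0.486, 2.07 paired-end). Each of the 7 fails the adjustment over all genes. Their log2 ratios of HF to IFE were 2.16, 2.11, 1.59, 1.20, -1.66, -0.84 and -1.56 in that order, and those of Lgr5 Epcam+ to K14 Epcam+ were -0.08, 0.19, -0.07, -0.17, 0.59, 0.95 and 0.21. The difference is in effect the second ratio minus the first. For all but Krtdap it came mostly from the difference between the normal samples, for which the lists hold known markers. Each difference rests on 1 HF, 1 IFE and 1 K14 Epcam+ sample. With samples centred in windows it was -1.99 for Lgr5, -2.49 for Tbx1, -1.57 for Lhx2, -0.96 for Fgf18, 1.71 for Krt1, 1.81 for Krtdap and 1.57 for Zfp750.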

How the results depend on the processing

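All alternatives were planned except window centring, chromosomes 1 to 14 alone, removal of pile-up peaks, background subtraction and the paired-end gene sums, which were chosen after the data were seen. For 329 values of named genes, 1971 alternative values were compared. Lost and gained calls were counted in the tested comparisons only, and reversals only where the main analysis made a call. On that count 0 reversed, 84 lost their call and 2 gained one. Of untested values 293 moved beyond a spread taken from the Lgr5 Epcam+ pair, and the other 1592 values were counted under none of these. An untested value that lost its call by the rule of size is therefore counted as moved or as unchanged. For 74 named peaks under 972 values the numbers in that order were 0, 9, 0, 146 and 817. The 146 that moved include tested comparisons judged by the rule of size. Most named genes and all named peaks were picked for large ratios in the main analysis, so 0 reversals says little about other calls. Of all 28867 peak calls in Lgr5 Epcam+ against HF, 46.1% were kept with loess scaling and 100% with DESeq2 size factors. Their ratios had the opposite sign at 10 peaks with loess scaling and at 13 with background subtraction. Of the alternative list medians 1 reversed, 285 moved and 578 did not: the median of the TGF-beta pathway in Lgr5 Epcam- tumour vs Lgr5 Epcam+ tumour was 0.12 and with centred windows -0.058. The cause was not tested for any of the changes that follow, except where fewer peaks, fewer samples or another limit are the alternative itself. Counts are peaks higher and lower.

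Limits on the log2 ratio: at 1, HF against IFE gave 13352 and 14671, K14 Epcam+ against IFE 37189 and 33526, Lgr5 Epcam- against HF 39930 and 35841, and Lgr5 Epcam+ sample 1 against 2 11709 and 14692; at 3, 316 and 0, 2825 and 2271, 2055 and 2862, and 27 and 124. Single-end runs gave 1756 and 284 for HF against IFE, 200 and 56 for Lgr5 Epcam+ against K14 Epcam+ and 19 and 5 for the difference between tumour changes. Paired-end runs gave 4614 and 2439, 6 and 26, 24 and 9, and 1368 and 2759 for the Lgr5 Epcam+ pair, with an EMT peak median of -0.030. For 1 run alone the rule of size lacks its limit in each run. Its calls for HF against IFE and for the pair therefore follow a looser rule than the main ones.

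Total-count scaling gave 481 lower for HF against IFE, 24418 lower for Lgr5 Epcam+ against HF, 14 and 75 for Lgr5 Epcam+ against K14 Epcam+, 26 and 51 for the difference, 69.4% of IFE-higher peaks kept and an EMT peak median of -0.14. DESeq2 size factors gave 8 higher for Lgr5 Epcam+ against K14 Epcam+ and 1 lower for the difference. Loess scaling gave 6435 higher for Lgr5 Epcam+ against HF, 7128 and 5229 for Lgr5 Epcam- against Lgr5 Epcam+ and an EMT peak median of -0.036. The DESeq2 test gave 7454 lower for Lgr5 Epcam+ against HF, 30 and 24 for Lgr5 Epcam+ against K14 Epcam+, 5683 higher for Lgr5 Epcam- against Lgr5 Epcam+ and 2 and 2 for the difference, and the rule of size 394 and 494 for Lgr5 Epcam+ against K14 Epcam+ and 2935 and 4650 for the difference, where it made 6180 false calls in simulated data.

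Leaving out either Lgr5 Epcam+ sample leaves no residual degree of freedom, so the rule of size was used. Ranges were 12280 to 15106 and 7934 to 12328 for Lgr5 Epcam+ against HF, 378 to 2157 and 754 to 1255 for Lgr5 Epcam+ against K14 Epcam+, 8012 to 12357 and 8499 to 10208 for Lgr5 Epcam- against Lgr5 Epcam+, 3696 to 4435 and 5524 to 6112 for the difference, 45.5% to 69.1% of HF-higher and 54.7% to 59.2% of IFE-higher peaks kept, r from -0.040 to 0.096, and EMT peak medians of 0.015 to 0.063.

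Background subtraction with the rule of size gave 13919 and 8668 for HF against IFE, 32624 and 25485 for K14 Epcam+ against IFE, 26920 and 25136 for Lgr5 Epcam+ against HF, 4933 and 5476 for Lgr5 Epcam+ against K14 Epcam+, 20314 and 20917 for Lgr5 Epcam- against Lgr5 Epcam+, 33006 and 30960 for Lgr5 Epcam- against HF, 13046 and 17817 for the difference, 4475 and 8485 for the Lgr5 Epcam+ pair, and an EMT peak median of -0.10. Without pile-up peaks the difference had 0 higher, which the removal itself fixes because the only called peak is 1 of them. Centred windows gave 0 lower for Lgr5 Epcam+ against K14 Epcam+, and chromosomes 1 to 14 gave 2 higher. The percentile of the EMT peak median was at most 0.6 under the alternatives run for it, which leave out DESeq2 size factors, the other limits and the other prior count. The planned motif comparison was not run for want of a genome sequence, and no paired analysis was possible because the labels pair no samples. With 1 residual degree of freedom, edgeR found 25.4% of simulated 4-fold changes in Lgr5 Epcam+ against HF and 0 for the difference. Few peaks were changed in the simulated data, which makes the adjusted threshold stricter than where many peaks change. These shares therefore do not tell how many measured changes of that size were missed in Lgr5 Epcam+ against HF. For the difference, where 1 peak was called, changes of that size may be mostly missed.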

Other observations

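All tests of explanations here were chosen after the results were seen. A scan for stretches where the running median over 11 peaks differed from the mean of the other 5 samples by a log2 ratio of at least 2 found loci with more or fewer counts in a single sample as a block. In HF there were 15 such stretches, including 1 over Lgr5 (chromosome 10, 115439831 to 115550863, median 2.38), 1 over Lhx2 (chromosome 2, 38347430 to 38373052, 2.25), 1 over Zbtb16, which encodes a zinc finger repressor (2.28), and 1 over the sortilin-family gene Sorcs3 (3.04). IFE had 8, including Gata3, a transcription factor of epidermal and follicle lineages (chromosome 2, 9833223 to 9870128, 2.28), and Clca3a2 (2.48), and 1 lower, over Vmp1 (-2.50). Lgr5 Epcam- had 9, over the collagen genes Col3a1 (2.11) and Col1a2 (2.93), over Lox (2.35) and in 6 places on chromosome 9, and 3 lower, over Dsp (-2.15), Tmem51 (-2.28) and Mill1 (-2.42). K14 Epcam+ had 1 and the Lgr5 Epcam+ samples 0. For these samples the mean of the other 5 includes closely similar Epcam+ tumour samples. A stretch shared by the Epcam+ tumours is therefore muted in this scan, and the numbers cannot be set against those of HF, IFE and Lgr5 Epcam-.

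The 6 stretches on chromosome 9 of Lgr5 Epcam- span 0.927 Mb with 339 peaks and a median log2 ratio of 3.46 (11-fold); the first, 7746943 to 8117403, holds Yap1, Birc2, Birc3, Cep126, Cfap300 and Tmem123, and others hold Dpy19l1, Smad6 and Vps13c. Uneven counting in 1 run is excluded, since the run with the smaller median still had 3.22. Extra copies of these segments in this tumour remain possible. The third of the peaks most open in the other samples rose as much as all of them (difference 0.093). That 336 of the 339 peaks were at least 2-fold higher is no separate support, because the scan picked stretches of high running median. Opening of single elements stays open: peaks cover the segments 4.48 times as densely as their flanks, between the bounds of 3 and 5 set for and against it. No DNA copy number was measured, and Lgr5 Epcam+ sample 1 also had more of its counts there (0.0891%) than sample 2 (0.0584%).

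The low counts of K14 Epcam+ from chromosome 15 to X may come from incomplete single-end counts, since its single-end over paired-end ratio steps by -0.93 within chromosome 15 while no other sample steps by more than 0.036. Loss of chromosome copies is excluded as the whole cause. On chromosomes 16 to X, against the other samples, the paired-end counts of the same cells dropped by only 0.115 of the single-end drop. Against chromosomes 1 to 14, the log2 median of K14 Epcam+ on chromosomes 16 to X was -1.04 single-end and -0.107 paired-end. Lgr5 Epcam+ sample 2 also had -0.107 paired-end. A step seen in 1 of the 2 runs of a sample argues against a biological cause of the step, if both runs hold the same cells. Why the single-end counts are low there stays open, and for the small paired-end drop no explanation beyond copy loss was tested.

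The 14 peaks lower in Lgr5 Epcam+ than in K14 Epcam+ had 336 counts over the 3 Lgr5 libraries where the counts outside peaks predict 1217, a ratio of 0.276. Closed chromatin at intact sequence would leave counts near that background, where the same peaks were in HF (1.04) and IFE (1.38). Only 58 of all 177240 peaks fell under 0.5 in the Lgr5 libraries. The pooled ratio cannot exclude closed chromatin for the set, because its peaks were picked for low Lgr5 Epcam+ counts. Sequence that is missing or not mappable in the Lgr5 tumours, as between mice of mixed strain, is consistent with the ratio for 11 of the 14, while 3 peaks (0.610, 0.654 and 1.74) are not that low. Whether sequence is missing at all, by a strain difference or a deletion in the tumours, stays open, and no variant was looked at.

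Of 8 peaks in the first 90 Mb of the Y chromosome, 6 had 142 to 355 counts in HF and 52 to 187 in IFE but 0 to 5 in each tumour sample, and all samples are labelled female. Any difference in sex between normal and tumour samples is confounded with every comparison of tumour with normal skin and was not tested. On K14 Epcam+ against IFE, chromosome 6 had medians of 0.75 to 0.91 from 120 to 150 Mb and of -0.35 to 0.45 before it. Between Lgr5 Epcam+ samples 1 and 2, the medians of chromosomes 16, 18 and 19 were 0.39, -0.31 and 0.57. At Trp53, the floxed gene, the peak at 69580767 to 69581979 on chromosome 11 had 16.2 CPM in K14 Epcam+, 16.4 in HF, 19.5 in IFE and 21 in Lgr5 Epcam-, with the Lgr5 Epcam+ samples between these. Which exons the floxed allele loses is not given in the sources used here, and the counts per peak do not resolve them.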
